A study of Mus musculus with 12 samples.

How the data were processed

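RNA from the soleus muscle of C57BL/6 mice was sequenced in 12 libraries, 3 in each of 4 groups: wild type (WT) and knockout (KO) mice, each sedentary or after exercise. The WT mice carried floxed Dnmt3a alleles, and the KO mice are named MCK-Dnmt3a KO in the labels. MCK usually means muscle creatine kinase, whose promoter is used to delete floxed genes in striated muscle. The labels' protocols name Trizol extraction, a spin column kit, a BGI library kit and a BGISEQ instrument. The exercise protocol, the time between exercise and dissection, the time of day and the deleted exons are not given in the sources used here.

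The values analysed were counts per gene, whole numbers in a table that the authors deposited for the whole series. STAR, featureCounts and the mouse genome build mm10 are named for these samples in the submitters' processing notes, with no role or order. Their versions, the gene annotation, the read length and whether counting used strand are not given in the sources used here. The table's 12 other columns of per-sample values were not used. Each count column carried a genotype, a condition and an animal number in its name. The animal numbers match no sample label, so each column was assigned to its group only. Within a group the libraries are called a, b and c in the order of the columns. The columns KO exercise a and WT exercise a carry 2 animal numbers each, and whether these libraries pooled animals is not given in the sources used here. The design text gives 3 mice per group, so the libraries of a group were treated as separate mice.

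Total counts ran from 13329547 to 15480960 per library. The table lists 24539 genes, among them 0 transcripts of the mitochondrial genome. No replicate pair agreed within sampling noise: over genes with at least 20 counts in the pair, the chi-square per gene between libraries of one group ran from 8.73 to 51.9, so all 12 libraries were kept as separate replicates. Among genes with at least 100 counts in all, 40 genes in 15 sets had the same 12 counts as another gene, for example Hba-a1 with Hba-a2, Hbb-bs with Hbb-b1 and Snrpn with Snurf. The reads of such near-identical or overlapping genes cannot be told apart, and their values are uncertain, as are those of the near-identical Hspa1a and Hspa1b.

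Genes were filtered with filterByExpr of edgeR on the 4 groups (minimum count 10), which left 13886 tested genes. Libraries were scaled with TMM factors. One quasi-likelihood model with a mean per group was fitted to all 12 libraries with glmQLFit (robust), giving 8 residual degrees of freedom, a median prior of 4.45 degrees of freedom and a common biological coefficient of variation of 0.168. Contrasts were tested with glmQLFTest, and p-values were adjusted by Benjamini and Hochberg over the tested genes, with a threshold of 0.05. The 6 planned contrasts were KO against WT in sedentary mice, KO against WT after exercise, exercise against sedentary in WT, exercise against sedentary in KO, the interaction of genotype and exercise, and KO against WT averaged over both conditions. The average of the exercise effect over both genotypes was added after the data had been seen. Standard errors are those of the log2 fold change. Levels are CPM (counts scaled to a common library size with the TMM factors, by edgeR's cpm), computed here from the counts, given as mean ± SD over the 3 libraries of a group. Adjusted p-values of single genes are from edgeR's quasi-likelihood test unless another tool is named.

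The 34 gene lists covered fibre type (slow and fast fibre contractile genes), metabolism (respiratory chain, mitochondrial genome transcripts, TCA cycle, fatty acid uptake and oxidation, glycogen breakdown and glycolysis, folate and one-carbon metabolism), responses to exercise and stress (immediate early genes, exercise-inducible metabolic regulators, antioxidant genes, heat shock genes, glucocorticoid response, atrophy and autophagy, circadian clock), epigenetic genes (DNA methylation machinery, germline genes silenced by methylation, imprinted genes), myogenic and denervation genes, extracellular matrix, cytokines, interferon response, and markers of other cells. The cell lists were adipocytes, endothelium, smooth muscle and pericytes, macrophages, neutrophils, lymphocytes, fibro-adipogenic progenitors, Schwann cells, erythrocytes, tendon and satellite cells, with 1 list of sex-linked genes. Each list with at least 2 tested genes was tested per contrast with camera of limma on log2 CPM (prior count 2), with the preset correlation between genes of 0.01, again with an estimated correlation, and with fry, which tests a list without comparing it with other genes. These p-values were adjusted over the lists of one contrast. The lists, the contrasts other than the added one, the tests and the rule for named genes were fixed before the data were examined.

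Genes were named by that rule: Dnmt3a and Aldh1l1, a gene that published work on this knockout names; the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups' libraries, leaving out predicted genes; up to 4 called members of each list, or up to 2 of a discussed list with none; and the 5 smallest p-values where a contrast had fewer than 5 calls. Not every gene this rule picks is described. Coordinates are 1-based on mm10 from GENCODE vM21, in which 97.9% of the tested symbols were found, or from RefSeq where stated. Without known strand the reads of genes whose exons overlap cannot be told apart. Beside those the report names, such overlaps hold for Dbp (with Sphk2), Arntl (Gm45355), Jun (Junos), Irs2 (9530052E02Rik), Cd34 (Gm16897), Pdgfra (Gm42802 and Gm42803), Hspa1a (Gm20481), Bhlhe40 (0610040F04Rik), Cebpd (Spidr), Mt2 (Gm45774), Notch3 (Gm17276), Pgm1 (Itgb3bp), Meg3 (Gm26906) and Shmt1 (Smcr8), and for Mirg, H19 and Hspa8 with small RNA genes.

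The gene-level test was run on simulated counts drawn from the real means, dispersions and library sizes and 200 genes changed by known folds. Of the genes changed 2-fold, it recovered 55.4% (KO in sedentary mice), 68.7% (KO after exercise), 70.1% (exercise in WT) and 62.7% (exercise in KO). It recovered 29.2% (interaction), 77.3% (averaged genotype) and 78.1% (averaged exercise). The list test called 1 of 1 raised and 0 of 20 unchanged lists. Correlated lists were not simulated, so their false calls were untested.

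The alternatives chosen beforehand were size factors of the DESeq2 kind, library size alone, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), DESeq2, limma-voom, a fit of the compared groups alone, a threshold of 0.1, glmTreat with a fold of 1.2, and each library left out in turn. Added after the data had been seen were fits without the 2 libraries of 2 animal numbers, without the 3 libraries in which Alb exceeded 100 CPM, with a covariate for the clock genes, for the fast fibre genes or for liver markers, without the liver marker genes, and rank correlations. Not analysed here are transcripts of the mitochondrial genome, lists with fewer than 2 tested genes (lymphocytes, with 1 tested gene), splice forms and DNA methylation. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.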

Results

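Gene expression was measured by RNA sequencing in the soleus, a mouse calf muscle rich in slow fibres, in 12 libraries: 3 from sedentary wild type (WT) mice, 3 from sedentary mice with a muscle knockout of Dnmt3a (KO), 3 from exercised WT mice and 3 from exercised KO mice. Dnmt3a encodes a de novo DNA methyltransferase. Total counts per library ran from 13329547 to 15480960, and 13886 of 24539 listed genes were tested. The mean over the group's 3 libraries is given with its SD, and fold changes are on the log2 scale with their standard error (SE). Alb, the main plasma protein made by liver, stood at 329 CPM in KO sedentary b, 227 in WT exercise b and 178 in WT exercise c, and at most at 20.6 CPM in the other 9 libraries. Dbp, a clock-controlled transcription factor, stood at 136 to 266 CPM in 5 libraries of all 4 groups and at 18.3 to 25.8 CPM in the other 7. Myh4, the fastest myosin heavy chain, stood at 5500 CPM in KO sedentary b and at 33.8 to 1740 CPM elsewhere.

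**Figure D1:**
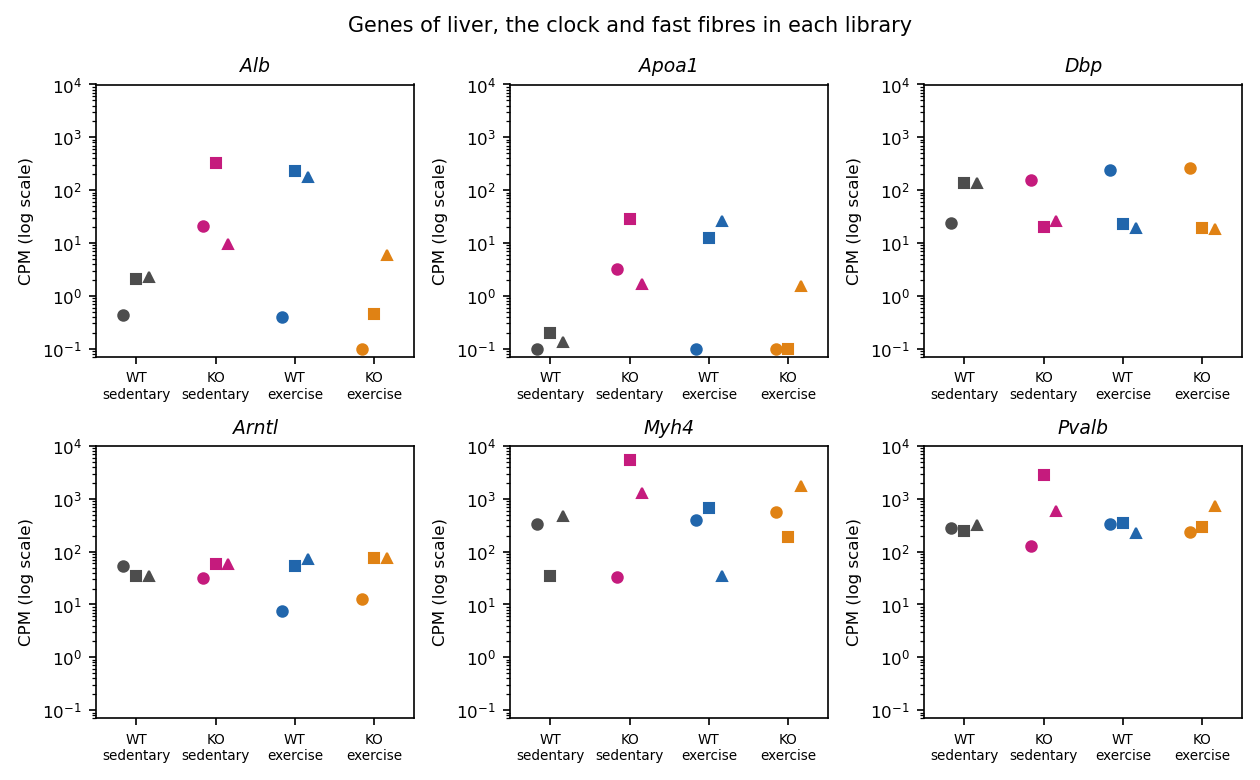
Each panel plots CPM (log scale, values of 0 drawn at 0.1) of 1 gene in the 12 libraries, by group and letter. Alb was above 100 CPM in KO sedentary b, WT exercise b and WT exercise c, Dbp was above 100 CPM in 5 libraries, and Myh4 was highest in KO sedentary b, at 5500 CPM.

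The targeted gene was lower in every KO library than in every WT library. Dnmt3a (chromosome 12, 3806007 to 3914443, plus strand, mm10) had 149 ± 26 CPM in sedentary WT, 50.2 ± 2.2 in sedentary KO, 135 ± 35 in exercised WT and 58.7 ± 1.6 in exercised KO muscle (n = 3 each). Averaged over both conditions it fell by 1.39 (SE 0.114, adjusted p = 0.000288), to 48.6 to 60.5 CPM in the 6 KO libraries against 113 to 180 in the 6 WT libraries. Its exons overlap those of Dnmt3aos on the other strand, and the strand of the reads is not known. Exons were not counted separately, so which part of the gene the remaining reads came from was not measured.

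KO was compared with WT in sedentary mice, which asks what the knockout of Dnmt3a changes in resting muscle. Ctxn3, which encodes a small membrane protein of the cortexin family (chromosome 18, 57468516 to 57478133), rose from 33.4 ± 2.2 to 67.3 ± 3.5 CPM, a change of 1.01 (SE 0.102, adjusted p = 0.00347). Mttp, the microsomal protein that loads lipid onto lipoproteins (chromosome 3, 138089854 to 138144968, exons overlapping Trmt10a and Gm43691), rose from 5.53 ± 0.43 to 11.8 ± 1.1 CPM, a change of 1.09 (SE 0.144, adjusted p = 0.0192). Kcne1l, an accessory subunit of voltage-gated potassium channels (chromosome X, 142304752 to 142306294), rose from 5.19 ± 1.6 to 14.3 ± 0.89 CPM, a change of 1.47 (SE 0.195, adjusted p = 0.0192). Dnmt3a fell by 1.57 (SE 0.162, adjusted p = 0.00347). The 3 rises and 1 fall were the only calls of edgeR among 13886 genes, while DESeq2 called 20 and limma-voom 3. At an unadjusted p under 0.05 there were 671 genes, where 694 would be expected by chance, and 1441 genes (10.4%) had no overlap between the groups, where chance gives 10%.

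Among the lists, antioxidant and folate genes held members that passed only when adjusted over the list alone, here called within the list. Gpx3, the extracellular glutathione peroxidase, went from 148 ± 22 to 283 ± 36 CPM (log2 0.94, adjusted p = 0.0893 over all genes), and Gpx1, its cytosolic relative, from 43.4 ± 5.2 to 68.4 ± 7.0 CPM (log2 0.66, adjusted p = 0.11); both passed within the list (adjusted p = 0.00064), the others of 25 antioxidant genes did not. Of 22 folate and one-carbon genes, 0 passed over all genes and 2 passed within the list: Aldh1l1, the cytosolic formyltetrahydrofolate dehydrogenase (chromosome 6, 90486427 to 90600203, exons overlapping Gm15756 and Gm45901), and Shmt1, a serine hydroxymethyltransferase. Aldh1l1 had 9.04 ± 1.4 CPM in WT and 21.1 ± 0.84 in KO muscle (log2 1.22, SE 0.247, adjusted p = 0.446), and Shmt1 3.9 ± 0.57 and 7.6 ± 1.1 CPM (log2 0.96, adjusted p = 0.276).

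Of the lists in sedentary mice camera called 9, none with an estimated correlation at an adjusted p under 0.05. There fry called 2: myogenic and denervation genes (fry adjusted p = 0.0302) and folate genes (median 0.11, fry adjusted p = 0.039, camera adjusted p = 0.1). Myogenic and denervation genes, which mark immature or denervated fibres, had positive changes in 15 of 16 members (median 0.30, camera adjusted p = 6.38e-05, adjusted p = 0.0654 with an estimated correlation, here the estimated-correlation p). Among them 0 passed over all genes and 3 within the list: Chrna1, the alpha subunit of the muscle acetylcholine receptor (log2 0.78), Chrng, its fetal gamma subunit (1.19), and Myh8, the perinatal myosin heavy chain (2.16). Fatty acid uptake and oxidation genes had negative changes in 20 of 20 members (median −0.15, camera adjusted p = 3.14e-06, estimated-correlation p = 0.444), with 0 past the threshold over all genes or within the list. Respiratory chain genes were negative in 64 of 73 (median −0.079, camera adjusted p = 0.000104, estimated-correlation p = 0.691). TCA cycle genes were negative in 13 of 14 (median −0.10, camera adjusted p = 0.00594, estimated-correlation p = 0.621). In both lists 0 genes passed over all genes or within the list. The 8 erythrocyte genes were all positive (median 1.01, camera adjusted p = 9.81e-08, estimated-correlation p = 0.423), with 0 past the threshold over all genes and 8 within the list; several of them share reads as near-identical globin genes. Hba-a1 stood at 193 CPM in KO sedentary b, 172 in c and 65.0 in a, against 60.8 ± 8.3 in sedentary WT, so 2 of the 3 KO libraries stood apart.

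Of the remaining called lists, imprinted genes had a median of 0.19 (camera adjusted p = 0.0264, estimated-correlation p = 0.423), with Rian, an imprinted noncoding RNA, at 0.91 and past the threshold within the list. Macrophage genes had a median of 0.76 (camera adjusted p = 0.00182, estimated-correlation p = 0.469), and this call was lost without KO sedentary b (median 0.21, adjusted p = 0.105). Smooth muscle and pericyte genes had a median of −0.24 (camera adjusted p = 0.00646, estimated-correlation p = 0.423). DNA methylation genes had a median of −0.065 (camera adjusted p = 0.026, estimated-correlation p = 0.423). Only the targeted Dnmt3a passed, and the list was not tested without it. No macrophage or smooth muscle gene passed either way. Calls were also lost for macrophage genes without WT sedentary b (median 0.56), for respiratory chain genes without WT sedentary c (median −0.040) and for smooth muscle genes without KO sedentary c (median −0.17). TCA cycle genes lost theirs without KO sedentary b, WT sedentary b or WT sedentary c (medians −0.092 to −0.053), DNA methylation genes without KO sedentary a or WT sedentary b (−0.073 to −0.056), and imprinted genes without KO sedentary b, KO sedentary c, WT exercise a, WT sedentary b or WT sedentary c (0.054 to 0.18). With the call kept, the median moved by more than 1.5 times for respiratory chain genes without KO sedentary b (−0.050) or WT sedentary a (−0.135), fatty acid genes without KO sedentary b (−0.073) or WT sedentary c (−0.077), DNA methylation genes without WT sedentary c (−0.106) and erythrocyte genes without KO sedentary c (0.65). The number of genes called fell to 1 without KO sedentary c and to 2 without KO exercise b, KO sedentary b or WT sedentary b. Ctxn3 was called in every alternative run, while Mttp lost its call without 7 of the 12 libraries in turn (changes 1.01 to 1.13), Kcne1l without 4 (1.43 to 1.55) and Dnmt3a without KO sedentary c (−1.55).

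In exercised mice, where KO was compared with WT for the state after exercise, Ctxn3, Mttp and Dnmt3a passed again. Ctxn3 had 35.0 ± 5.0 CPM in WT and rose to 86.2 ± 3.0 in KO muscle, a change of 1.30 (SE 0.102, adjusted p = 0.000242). Mttp rose from 7.63 ± 0.13 to 16.7 ± 2.9 CPM, a change of 1.13 (SE 0.141, adjusted p = 0.0198), and Dnmt3a fell by 1.21 (SE 0.161, adjusted p = 0.0334). Next by p were Kcne1l, at 6.05 ± 0.78 and 13.6 ± 0.56 CPM (log2 1.17, adjusted p = 0.157), and 5930403L14Rik, a long noncoding RNA (log2 1.39, adjusted p = 0.157). Aldh1l1 stood at 8.55 ± 2.8 and 17.5 ± 5.9 CPM (log2 1.04, SE 0.251, adjusted p = 1), past the threshold only within the list (adjusted p = 0.0308). These 3 calls of edgeR compare with 9 by DESeq2 and 3 by limma-voom. In this comparison 469 genes had an unadjusted p under 0.05, and 994 (7.16%) had no overlap between groups, where chance gives 10%. Without KO exercise a or KO exercise b, or in a fit of the compared groups alone, 1 call was left. Dnmt3a lost its call without 7 of the 12 libraries in turn (changes −1.23 to −1.19) and Mttp without 5 (0.98 to 1.16).

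In the same comparison camera called 7 lists, none with an estimated correlation, and fry called 0. Immediate early genes, the transcription factors that respond first to contraction, had negative changes in 21 of 24 members (median −0.25, camera adjusted p = 0.00389, estimated-correlation p = 0.67), and this call was lost without KO exercise a (median −0.12, adjusted p = 0.447). Glucocorticoid response genes were negative in 14 of 14 (median −0.46, camera adjusted p = 0.0131, estimated-correlation p = 0.67). Endothelial genes were negative in 10 of 10 (median −0.23, camera adjusted p = 8.93e-05, estimated-correlation p = 0.665), with a median of −0.12 and the call kept without KO exercise c. Interferon response genes were negative in 14 of 14 (median −0.24, camera adjusted p = 0.0117, estimated-correlation p = 0.67). Extracellular matrix genes were negative in 19 of 20 (median −0.21, camera adjusted p = 0.0166, estimated-correlation p = 0.919), and the median turned positive without KO exercise c (0.019) or WT exercise b (0.12), with the call lost also without KO exercise a (−0.15). Heat shock genes were positive in 15 of 22 (median 0.13, camera adjusted p = 0.0258, estimated-correlation p = 0.876). Glucocorticoid genes lost the call without KO exercise b or WT exercise a (medians −0.26 to −0.14), interferon genes without KO exercise a, KO exercise c or WT exercise c (−0.22 to −0.13), and heat shock genes without KO exercise c, WT exercise a or WT exercise b (0.035 to 0.15). Imprinted genes, the seventh list, lost it without KO exercise a, KO exercise b, WT exercise a or WT sedentary c (0.069 to 0.15). With the call kept, the median moved by more than 1.5 times for immediate early genes without KO exercise c (−0.55), extracellular matrix genes without KO exercise b (−0.57) or WT exercise a (−0.38), interferon genes without KO exercise b (−0.375) and imprinted genes without WT exercise b (0.18). In the first 6 lists 0 genes passed over all genes or within the list. Among imprinted genes (median 0.11, camera adjusted p = 0.044, estimated-correlation p = 0.67), the noncoding RNAs Mirg (log2 1.76) and Rian (log2 1.00) and the imprinted protein-coding gene Ndn (log2 −0.46) passed within the list, and 0 passed over all genes.

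Averaged over both conditions, KO muscle had 7 genes that rose and 1 that fell. Ctxn3 rose by 1.15 (SE 0.0723, adjusted p = 1.6e-05), Kcne1l by 1.32 (SE 0.137, adjusted p = 0.00142) and Mttp by 1.11 (SE 0.1, adjusted p = 0.000395). Chrna1 (chromosome 2, 73563215 to 73580338) rose by 0.63 (SE 0.0924, adjusted p = 0.0358), from 50.9 ± 7.5 to 87.6 ± 9.0 CPM in sedentary and from 59.4 ± 8.9 to 82.6 ± 5.9 CPM in exercised mice. Rian, an imprinted RNA whose exons overlap small nucleolar RNA genes (chromosome 12, 109603940 to 109661716), rose by 0.96 (SE 0.143, adjusted p = 0.0369). Dhdh, a dihydrodiol dehydrogenase (chromosome 7, 45470987 to 45488805, exons overlapping Tulp2 and Gm45808), rose by 0.81 (SE 0.122, adjusted p = 0.0371), and 5930403L14Rik (chromosome 4, 154630691 to 154636367, RefSeq) by 1.13 (SE 0.161, adjusted p = 0.0317). Aldh1l1 had a change of 1.13 (SE 0.176) and an adjusted p of 0.0545 over all genes, and passed within the list (adjusted p = 0.000776). Shmt1 (log2 0.64, adjusted p = 0.197) was the other of 22 folate genes that passed within the list (adjusted p = 0.00312). With a covariate for the clock genes, added after the data had been seen, Aldh1l1 rose by 1.22 (adjusted p = 2.59e-05, in a range of 1.92e-06 to 0.503 over all alternatives). Mttp and Aldh1l1 are also expressed in liver; in KO exercise b, with 16.3 CPM in the sum of 25 liver markers, Mttp stood at 16 and Aldh1l1 at 14.1 CPM, against 7.72 and 7.53 CPM in WT exercise b, with 440.

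**Figure D2:**
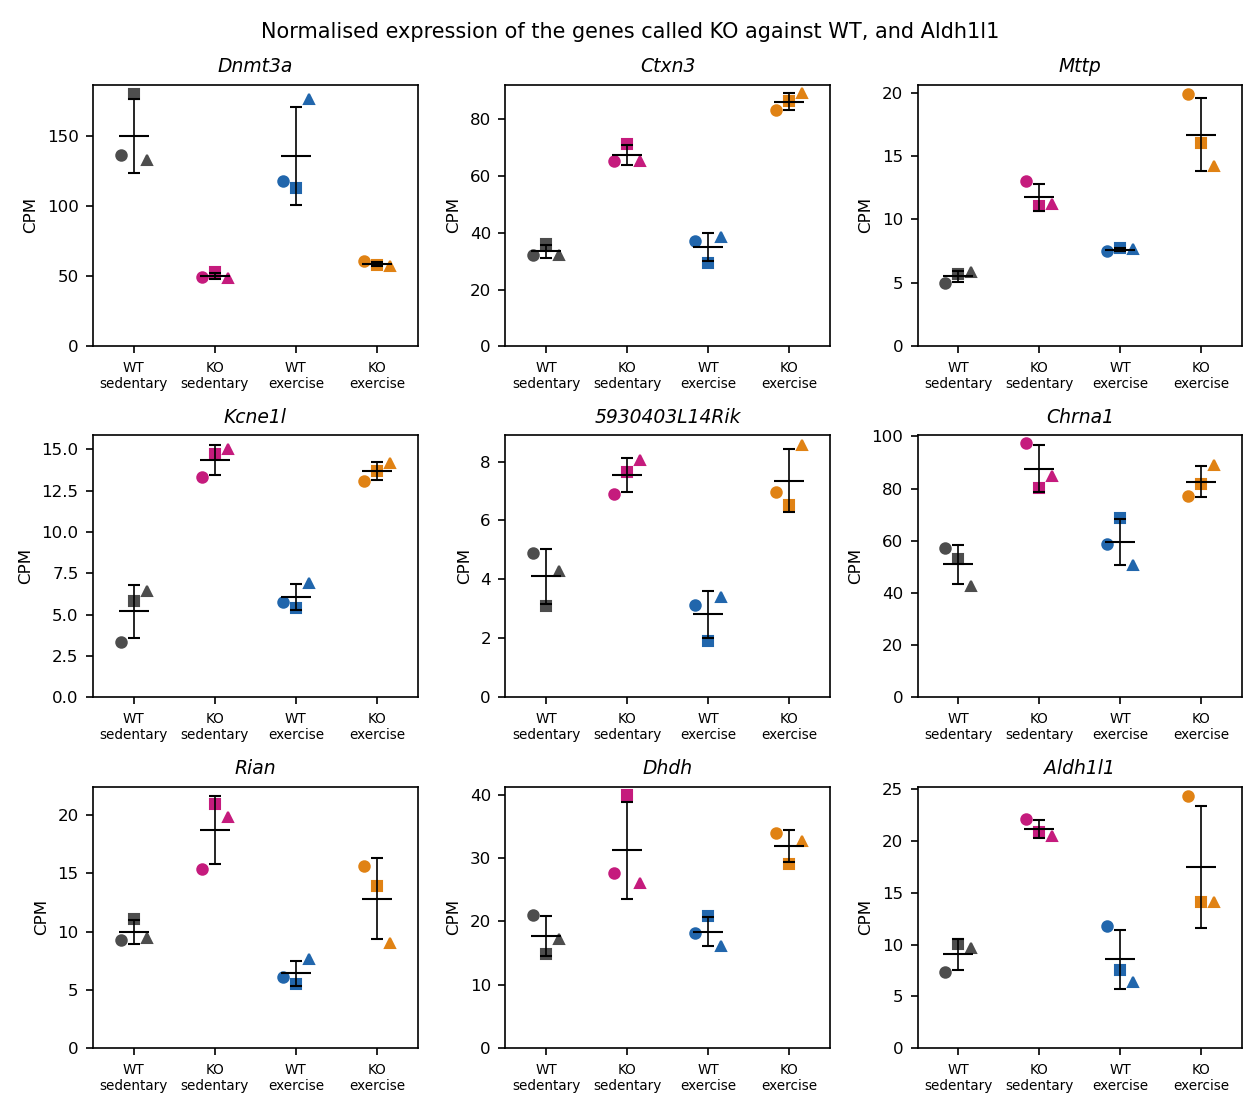
Each panel plots CPM of 1 gene in the 12 libraries by group (points, with shapes for letters a, b and c) with the group's mean ± SD (n = 3). Dnmt3a lay between 48.6 and 60.5 CPM in the KO libraries and between 113 and 180 in the WT libraries, and Ctxn3 averaged 67.3 and 86.2 CPM in sedentary and exercised KO muscle against 33.4 and 35.0 in WT.

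Of the lists, camera called 8 for the averaged genotype contrast, none with an estimated correlation, and fry called 0. Myogenic and denervation genes were positive in 15 of 16 (median 0.22, camera adjusted p = 9.99e-05, estimated-correlation p = 0.0615); 1 of them, Chrna1, passed over all genes and 3 passed within the list, with Myh8 at 2.26 and Chrng at 0.91 as the others. Imprinted genes had a median of 0.094 (camera adjusted p = 0.00565, estimated-correlation p = 0.486), with 1 rise over all genes, Rian, and 3 within the list: Rian, Mirg (log2 1.32) and H19 (log2 0.43), all of them noncoding RNAs. Fatty acid genes were negative in 20 of 20 (median −0.099, camera adjusted p = 0.000158, estimated-correlation p = 0.651), and the call was lost without KO sedentary b (median −0.058, adjusted p = 0.0604). Endothelial genes were negative in 10 of 10 (median −0.17, camera adjusted p = 9.99e-05, estimated-correlation p = 0.486). Smooth muscle and pericyte genes were negative in 8 of 8 (median −0.15, camera adjusted p = 0.00535, estimated-correlation p = 0.486). Glucocorticoid response genes were negative in 14 of 14 (median −0.29, camera adjusted p = 0.0204, estimated-correlation p = 0.651). Interferon genes were negative in 13 of 14 (median −0.13, camera adjusted p = 0.00397, estimated-correlation p = 0.651). Erythrocyte genes were positive in 8 of 8 (median 0.34, camera adjusted p = 0.00599, estimated-correlation p = 0.651), from medians of 1.01 in sedentary and −0.27 in exercised mice (negative in 8 of 8, camera adjusted p = 0.0988). No gene of these 6 lists passed over all genes or within the list. The call was also lost for imprinted genes without KO exercise b (median 0.055), for interferon genes without KO sedentary a (−0.13), for erythrocyte genes without KO exercise a, KO sedentary b, KO sedentary c or WT exercise c (0.17 to 0.32), and for glucocorticoid genes without KO exercise b, KO sedentary b, KO sedentary c, WT exercise a or WT sedentary b (−0.29 to −0.12). With the call kept, the median moved by more than 1.5 times for myogenic genes without KO sedentary a (0.14) or WT exercise c (0.13), imprinted genes without KO sedentary b (0.061) or WT exercise b (0.149), fatty acid genes without WT exercise b (−0.062) and interferon genes without KO exercise a (−0.22), b (−0.22) or c (−0.078). Outside the called lists, Gpx3 (log2 0.62, adjusted p = 0.0731) and Gpx1 (log2 0.32, adjusted p = 0.485) passed within the list, and of 14 DNA methylation genes only Dnmt3a passed either way. By edgeR 625 genes had an unadjusted p under 0.05, where 694 are expected; DESeq2 called 33 genes and limma-voom 8. The count fell to 4 without KO exercise a, KO exercise b, KO sedentary b, WT sedentary b or WT sedentary c, to 5 without KO sedentary c, and to 2 without the 3 libraries rich in Alb. That last fit had 1 exercised WT library, taken to vary like the other groups, and 5 residual degrees of freedom in place of 8. In it Kcne1l (log2 1.34, SE 0.196, adjusted p = 0.121) and Mttp (log2 1.14, SE 0.149, adjusted p = 0.0749) no longer passed. Their changes were about as large as in all libraries (1.32 and 1.11) and their SE larger, so the loss does not point to liver as their source. With 1 library left out in turn, Chrna1 and Rian each lost the call for 10 of the 12 libraries (changes 0.57 to 0.66 and 0.87 to 1.03), Dhdh for 9 (0.70 to 0.86) and 5930403L14Rik for 7 (1.05 to 1.17), with no change of direction.

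Exercise was compared with the sedentary state in WT mice, which asks how normal soleus responds. Slc25a25, a mitochondrial carrier of ATP-Mg and phosphate (chromosome 2, 32414487 to 32451445, exons overlapping Naif1), rose from 21.7 ± 9.7 to 114 ± 16 CPM, a change of 2.40 (SE 0.297, adjusted p = 0.0416). Fosl2, an AP-1 transcription factor (chromosome 5, 32135801 to 32157842), rose from 30.9 ± 4.8 to 57.0 ± 5.9 CPM, a change of 0.88 (SE 0.121, adjusted p = 0.0416). Akap5, an anchor of protein kinase A (chromosome 12, 76324891 to 76334153), fell from 7.54 ± 1.3 to 1.70 ± 0.51 CPM, a change of −2.13 (SE 0.279, adjusted p = 0.0416). Next by p were Gja4, an endothelial gap junction protein (log2 −1.10, adjusted p = 0.113), and Klf11, a Krüppel-like transcription factor (log2 0.97, adjusted p = 0.113). Dnmt3a (log2 −0.14, adjusted p = 0.822) and Aldh1l1 (log2 −0.087, adjusted p = 0.94) did not pass. The 3 calls of edgeR compare with 122 by DESeq2 and 2 by limma-voom, while 1306 genes had an unadjusted p under 0.05, and 2129 (15.3%) had no overlap between groups, where chance gives 10%. The number of calls was 0 without any of 9 of the libraries, 1 without WT sedentary c, 6 without KO exercise c and 8 without WT sedentary b.

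In WT mice the lists of responses to contraction and stress were positive, and camera called 17 lists, none with an estimated correlation. There fry called 3: immediate early (fry adjusted p = 0.00982), antioxidant and satellite cell genes (both fry adjusted p = 0.0482). Immediate early genes were positive in 24 of 24 (median 1.08, camera adjusted p = 5.71e-19, estimated-correlation p = 0.0842), with 1 rise over all genes and 12 within the list, among them Atf3 (log2 3.66) and Fos (log2 2.78). Heat shock genes were positive in 17 of 22 (median 0.26, camera adjusted p = 7.46e-06, estimated-correlation p = 0.302), with 0 rises over all genes and 6 within the list, among them Hspa8, the constitutive cytosolic chaperone (log2 0.41). Glucocorticoid response genes were positive in 14 of 14 (median 0.91, camera adjusted p = 2.15e-07, estimated-correlation p = 0.243), with 0 over all genes and 4 within the list, Errfi1, Tsc22d3, Mt2 and Cebpd. Exercise-inducible metabolic regulators had a median of 0.12 (camera adjusted p = 0.00648, estimated-correlation p = 0.302), with Sik1, a salt-inducible kinase (log2 2.26), and Irs2, an insulin receptor substrate (log2 2.46), past the threshold within the list. Atrophy and autophagy genes had a median of 0.25 (camera adjusted p = 0.00135, estimated-correlation p = 0.381). Antioxidant genes had a median of 0.10 (camera adjusted p = 0.00152, estimated-correlation p = 0.214). Slow fibre genes had a median of 0.15 (camera adjusted p = 0.043, estimated-correlation p = 0.627). Respiratory chain genes had a median of 0.083 (positive in 71 of 73, camera adjusted p = 5.97e-05, estimated-correlation p = 0.627). TCA cycle genes had a median of 0.056 (camera adjusted p = 0.0409, estimated-correlation p = 0.627). Slow fibre genes lost the call without each of 7 libraries (medians 0.015 to 0.16), respiratory chain genes without WT sedentary a (0.024), TCA cycle genes without WT exercise a or WT sedentary a (0.0073 to 0.029) and atrophy genes without WT exercise a (0.12). With the call kept, the median moved by more than 1.5 times for slow fibre genes without WT exercise b (0.23) or WT sedentary b (0.29), metabolic regulators without WT exercise a (0.24) or WT sedentary c (0.26), respiratory chain genes without WT exercise a (0.049), b (0.129) or c (0.054) or WT sedentary c (0.129), and TCA cycle genes without WT exercise b, WT sedentary b or WT sedentary c (0.086 to 0.096). In these last 5 lists 0 genes passed over all genes or within the list.

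In the same WT comparison the lists of vessels and connective tissue were negative. Endothelial genes were negative in 9 of 10 (median −0.32, camera adjusted p = 6.5e-05, estimated-correlation p = 0.243), with 0 falls over all genes and 6 within the list, among them Tie1 (log2 −0.33) and Egfl7 (log2 −0.57), both expressed by endothelium. Smooth muscle and pericyte genes (median −0.30, camera adjusted p = 0.00375, estimated-correlation p = 0.302) held Pdgfrb and Notch3 past the threshold within the list. Satellite cell genes (median −0.30, camera adjusted p = 0.0331, estimated-correlation p = 0.243) held Heyl, Notch3 and Pax7. Extracellular matrix genes had a median of −0.32 (camera adjusted p = 0.000348, estimated-correlation p = 0.627). Fibroblast genes had a median of −0.30 (camera adjusted p = 0.00166, estimated-correlation p = 0.5). Interferon genes had a median of −0.36 (camera adjusted p = 0.000348, estimated-correlation p = 0.302). Cytokine genes had a median of −0.61 (camera adjusted p = 0.0475, estimated-correlation p = 0.458). Macrophage genes had a median of −0.39 (camera adjusted p = 0.0318, estimated-correlation p = 0.627). In these last 5 lists 0 genes passed over all genes or within the list, and in the first 3 lists 0 passed over all genes. Cytokine genes lost the call without each of 11 libraries (medians −0.66 to −0.28), macrophage genes without WT exercise a, WT exercise c, WT sedentary a or WT sedentary c (−0.34 to −0.22) and fibroblast genes without WT sedentary a (−0.17). With the call kept, the median moved by more than 1.5 times for interferon genes without WT exercise a (−0.23), and for matrix (−0.65), cytokine (−1.04), macrophage (−0.66) and fibroblast genes (−0.49) without WT exercise b, which stood at 0.386 in the matrix list against −0.515 and −0.368. Satellite cell genes lost it without WT exercise b, WT sedentary a or WT sedentary c (−0.27 to −0.15), and smooth muscle genes without WT exercise b (−0.18).

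In KO mice, where the same exercise comparison asks how soleus without Dnmt3a responds, edgeR called 0 genes, with 2492 at an unadjusted p under 0.05 and a smallest adjusted p of 0.119; DESeq2 called 359 and limma-voom 0. The 5 genes with the smallest p all stood at that adjusted p of 0.119. They were Akap5 (7.25 ± 1.6 to 2.12 ± 0.6 CPM, log2 −1.77), Gbp4, an interferon-induced GTPase whose exons overlap Gbp8 and Gbp9 (log2 −0.91), Hspa8 (215 ± 21 to 311 ± 17 CPM, log2 0.53), the immediate early gene Ier5 (log2 1.72) and the noncoding RNA BB123696 (log2 3.51). Slc25a25 had 27.4 ± 5.3 and 93.1 ± 15 CPM and Fosl2 34.1 ± 2.6 and 53.2 ± 4.6 CPM, in the direction of their change in WT. Dnmt3a (log2 0.23, adjusted p = 0.463) and Aldh1l1 (log2 −0.27, adjusted p = 0.559) did not pass. Groups did not overlap in 3157 genes (22.7%), where chance gives 10%. The count was 4 without KO exercise a, 2 without KO sedentary a, 1 without WT exercise a, WT sedentary b or WT sedentary c, 6 without the 2 libraries of 2 animal numbers, and 7 in a fit of the KO groups alone.

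Of the lists in KO mice, camera called 20, none with an estimated correlation. There fry called 3: endothelial genes and sex-linked genes (both fry adjusted p = 0.0148) and neutrophil genes (fry adjusted p = 0.0349). Over all genes 0 members of any list passed. Heat shock genes were positive in 21 of 22 (median 0.29, camera adjusted p = 6.35e-07, estimated-correlation p = 0.342), with 11 rises within the list. Immediate early genes were positive in 18 of 24 (median 0.55, camera adjusted p = 1.12e-05, estimated-correlation p = 0.347), with 9 rises within the list, and a median of 0.96 with the call kept without KO sedentary a. Slow fibre genes were positive in 11 of 11 (median 0.34, camera adjusted p = 2.33e-05, estimated-correlation p = 0.356). Respiratory chain genes were positive in 70 of 73 (median 0.18, camera adjusted p = 1.09e-13, estimated-correlation p = 0.372). TCA cycle genes were positive in 14 of 14 (median 0.16, camera adjusted p = 0.000121, estimated-correlation p = 0.386). Fatty acid genes had a median of 0.069 (camera adjusted p = 0.0208, estimated-correlation p = 0.579). Glucocorticoid genes had a median of 0.72 (camera adjusted p = 0.000515, estimated-correlation p = 0.347). Atrophy genes had a median of 0.19 (camera adjusted p = 0.00754, estimated-correlation p = 0.386). Metabolic regulators had a median of 0.16 (camera adjusted p = 0.0468, estimated-correlation p = 0.386). Sex-linked genes had a median of 0.19 (camera adjusted p = 0.023, estimated-correlation p = 0.342). Among the other 8 lists named here with heat shock and immediate early genes, Sik1 (log2 1.44) was the only gene that passed within the list. Fatty acid genes lost the call without KO exercise c or KO sedentary b (medians −0.019 to 0.065, with the call kept at 0.106 to 0.136 without KO exercise b, KO sedentary a or KO sedentary c), sex-linked genes without KO exercise b or KO sedentary c (0.16 to 0.18), and metabolic regulators without KO exercise b, KO exercise c, KO sedentary b, WT exercise c, WT sedentary a or WT sedentary b (0.094 to 0.23).

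In exercised KO muscle erythrocyte genes were negative in 8 of 8 (median −1.27, camera adjusted p = 1.44e-05, estimated-correlation p = 0.347), with 8 falls within the list. They stood at 1.05 and 1.32 (mean of centred log2 CPM) in KO sedentary b and c, and at −0.124 in KO sedentary a, close to exercised KO muscle (−0.661 to −0.137). Macrophage genes were negative in 10 of 10 (median −1.25, camera adjusted p = 9.12e-06, estimated-correlation p = 0.347), also with 8 falls within the list, among them the complement genes C1qa (log2 −1.31) and C1qb (log2 −1.45). In the macrophage genes KO sedentary b stood at 1.38 and the other libraries of that group at 0.255 and 0.379. Without KO sedentary b the median was −0.77 with the call kept. Both neutrophil genes tested, Mmp9 and Csf3r, fell within the list (median −2.45, camera adjusted p = 0.0208, estimated-correlation p = 0.342). They too were highest in KO sedentary b, at 2.0 against 0.37 and 0.0176 in that group. Without it the median was −1.25 (camera adjusted p = 0.0313). Endothelial genes were negative in 9 of 10 (median −0.50, camera adjusted p = 1.12e-05, estimated-correlation p = 0.342), with 7 falls within the list. Fibroblast genes were negative in 10 of 10 (median −0.45, camera adjusted p = 0.000714, estimated-correlation p = 0.386), with Smoc2, Pdgfra and Cd34 past that threshold. Extracellular matrix genes had a median of −0.66 (camera adjusted p = 5.91e-07, estimated-correlation p = 0.386), and with the call kept of −0.42 without KO exercise c and −1.0 without KO exercise b. Interferon genes had a median of −0.50 (camera adjusted p = 0.000192, estimated-correlation p = 0.347). Cytokine genes had a median of −1.23 (camera adjusted p = 0.00561, estimated-correlation p = 0.347). Adipocyte genes had a median of −1.01 (camera adjusted p = 0.0468, estimated-correlation p = 0.552). Tendon genes had a median of −0.66 (camera adjusted p = 0.0353, estimated-correlation p = 0.527). In these last 5 lists Socs3 (log2 −1.29), Stat2 (log2 −0.51) and Bst2 (log2 −0.59) passed within the list. Adipocyte genes lost the call without KO exercise c, KO sedentary a, KO sedentary b or any exercised WT library (medians −1.01 to −0.61), and tendon genes without KO exercise a, KO exercise c, KO sedentary a or WT exercise a (−0.65 to −0.23, with the call kept at −1.28 without KO exercise b). Gpx3 (log2 −0.60) and Gpx1 (−0.44, both adjusted p = 0.147) fell within the list, opposite to the KO effect at rest, which shares the sedentary KO libraries.

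Averaged over both genotypes, a contrast added after the data had been seen, exercise raised 89 genes and lowered 233. Among the named genes Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039), rose most, by 3.56 (SE 0.527, adjusted p = 0.0159), from 23.1 ± 16 to 292 ± 120 CPM in WT and from 26.9 ± 13 to 296 ± 220 CPM in KO mice. Otud1, a deubiquitinase, rose by 2.84 (SE 0.514, adjusted p = 0.0294), and the orphan nuclear receptors Nr4a3 and Nr4a2 rose by 2.48 and 2.47. The noncoding RNA BB123696 rose by 3.09, the antiproliferative gene Btg2 by 2.37, and the near-identical inducible chaperone genes Hspa1b and Hspa1a by 2.52 and 2.30, all with adjusted p-values between 0.0118 and 0.0444. Among the falls, Akap5 changed by −1.95 (SE 0.195, adjusted p = 0.00351), Aplnr, the apelin receptor, by −2.02 (SE 0.329, adjusted p = 0.0234) and Mycn by −2.18. Of genes expressed by leukocytes, Evi2b, whose exons overlap Evi2, fell by 1.57, Ptafr, the receptor of platelet-activating factor, by 1.55 and the adaptor Themis2 by 1.51. Bcl6b, a transcriptional repressor, fell by 1.40. Dnmt3a had a change of 0.042 (adjusted p = 0.855) and Aldh1l1 one of −0.18 (adjusted p = 0.564). DESeq2 called 1012 genes and limma-voom 317, 3170 had an unadjusted p under 0.05, and leaving out 1 library gave from 45 calls (without WT sedentary c) to 697 (without KO exercise b). Without the 3 libraries rich in Alb there were 122 calls, and without the 2 libraries of 2 animal numbers 123.

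Among the lists that were positive in this averaged contrast, immediate early genes had 9 rises over all genes and 12 within the list out of 24 (median 0.74, camera adjusted p = 1.43e-11, estimated-correlation p = 0.266). Fosl2 rose by 0.76, Ier5 by 1.61 and Jun by 1.35. Heat shock genes had 6 rises over all genes and 13 within the list out of 22 (median 0.30, camera adjusted p = 2.51e-07, estimated-correlation p = 0.266), with Hspa8 at 0.47, the small heat shock protein Hspb1 at 0.70 and the stress factor Atf4 at 0.31. Glucocorticoid response genes had 2 rises over all genes, Errfi1 (1.11) and Tsc22d3 (1.01), and 9 within the list out of 14 (median 0.88, camera adjusted p = 3.18e-06, estimated-correlation p = 0.266). Sik1 (1.85) and Irs2 (2.25) rose over all genes and within the list among 16 metabolic regulators (median 0.15, camera adjusted p = 0.012, estimated-correlation p = 0.312). Ddit4, an inhibitor of mTORC1 signalling (log2 2.07), passed within the list among atrophy genes (median 0.24, camera adjusted p = 0.000856, estimated-correlation p = 0.312). Slow fibre genes had a median of 0.24 (camera adjusted p = 0.000201, estimated-correlation p = 0.318). Respiratory chain genes had a median of 0.14 (positive in 71 of 73, camera adjusted p = 9.37e-12, estimated-correlation p = 0.318). TCA cycle genes had a median of 0.11 (camera adjusted p = 0.000367, estimated-correlation p = 0.371). In these 3 lists 0 genes were called over all genes or within the list. Antioxidant genes had a median of 0.095 (camera adjusted p = 0.0344, estimated-correlation p = 0.277). Sex-linked genes had a median of 0.14 (camera adjusted p = 0.0236, estimated-correlation p = 0.266). Antioxidant genes lost the call without WT exercise b (0.083), and glucocorticoid genes kept it without WT exercise a, at a median of 0.52.

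Among the lists that were negative in the averaged contrast, endothelial genes had 5 falls over all genes and 7 within the list out of 10 (median −0.42, camera adjusted p = 5.84e-06, estimated-correlation p = 0.266). Egfl7, an endothelial secreted protein whose exons overlap Agpat2, fell by 0.65, Pecam1 by 0.41, the mucin Emcn by 0.39 and the receptor Tie1 by 0.35. Pecam1 went from 223 ± 16 to 179 ± 6.5 CPM in WT and from 206 ± 7.4 to 146 ± 24 CPM in KO mice. Fibroblast genes had 3 falls over all genes, Cd34 (−0.56), Pdgfra (−0.53) and Smoc2 (−0.40), and 4 within the list out of 10 (median −0.36, camera adjusted p = 0.000267, estimated-correlation p = 0.318). Extracellular matrix genes had 1 fall over all genes, Col4a2 (−0.54, exons overlapping Col4a1), and 9 within the list out of 20 (median −0.54, camera adjusted p = 5.59e-07, estimated-correlation p = 0.334). Interferon genes had 1, the transcription factor Stat2 (−0.42), and 8 within the list out of 14 (median −0.42, camera adjusted p = 3.61e-05, estimated-correlation p = 0.277). Macrophage genes had 0 and 8 within the list out of 10 (median −0.83, camera adjusted p = 5.05e-05, estimated-correlation p = 0.312). Socs3, an inhibitor of cytokine signalling, fell by 0.99 in the cytokine list (median −0.94, camera adjusted p = 0.00634, estimated-correlation p = 0.291). Pdgfrb fell by 0.49 among smooth muscle and pericyte genes (median −0.24, camera adjusted p = 0.0133, estimated-correlation p = 0.312). Neutrophil genes had a median of −1.49 (camera adjusted p = 0.044, estimated-correlation p = 0.277). Erythrocyte genes had a median of −0.57 (camera adjusted p = 0.00795, estimated-correlation p = 0.458), from 0.036 in WT (4 of 8 positive) and −1.27 in KO mice, where KO sedentary b and c stood apart. Tendon genes had a median of −0.37 (camera adjusted p = 0.044, estimated-correlation p = 0.503). Tendon genes lost the call without each of 6 libraries (medians −0.37 to −0.16, with the call kept at −0.76 without KO exercise b and −0.56 without WT exercise b), neutrophil genes without KO exercise a, KO exercise b or WT sedentary a (−1.64 to −1.38, with the call kept at −0.89 without KO sedentary b), and smooth muscle genes without WT exercise b (−0.19). Heyl, an effector of Notch signalling, fell by 0.60 (SE 0.11, adjusted p = 0.0234), while the satellite cell list it belongs to was called by fry (fry adjusted p = 0.0223) and not by camera (camera adjusted p = 0.133). Imprinted genes were not called (median −0.25, negative in 12 of 19, camera adjusted p = 0.231). Of them Impact, a regulator of translation, rose over all genes, by 1.27 (SE 0.211, adjusted p = 0.0214), and Rian (log2 −0.59), Meg3 (−0.54) and Sgce (−0.34) fell within the list. In this contrast fry called 12 lists, 11 of them also called by camera, with the smallest fry adjusted p (0.00432) for immediate early and endothelial genes.

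**Figure D3:**
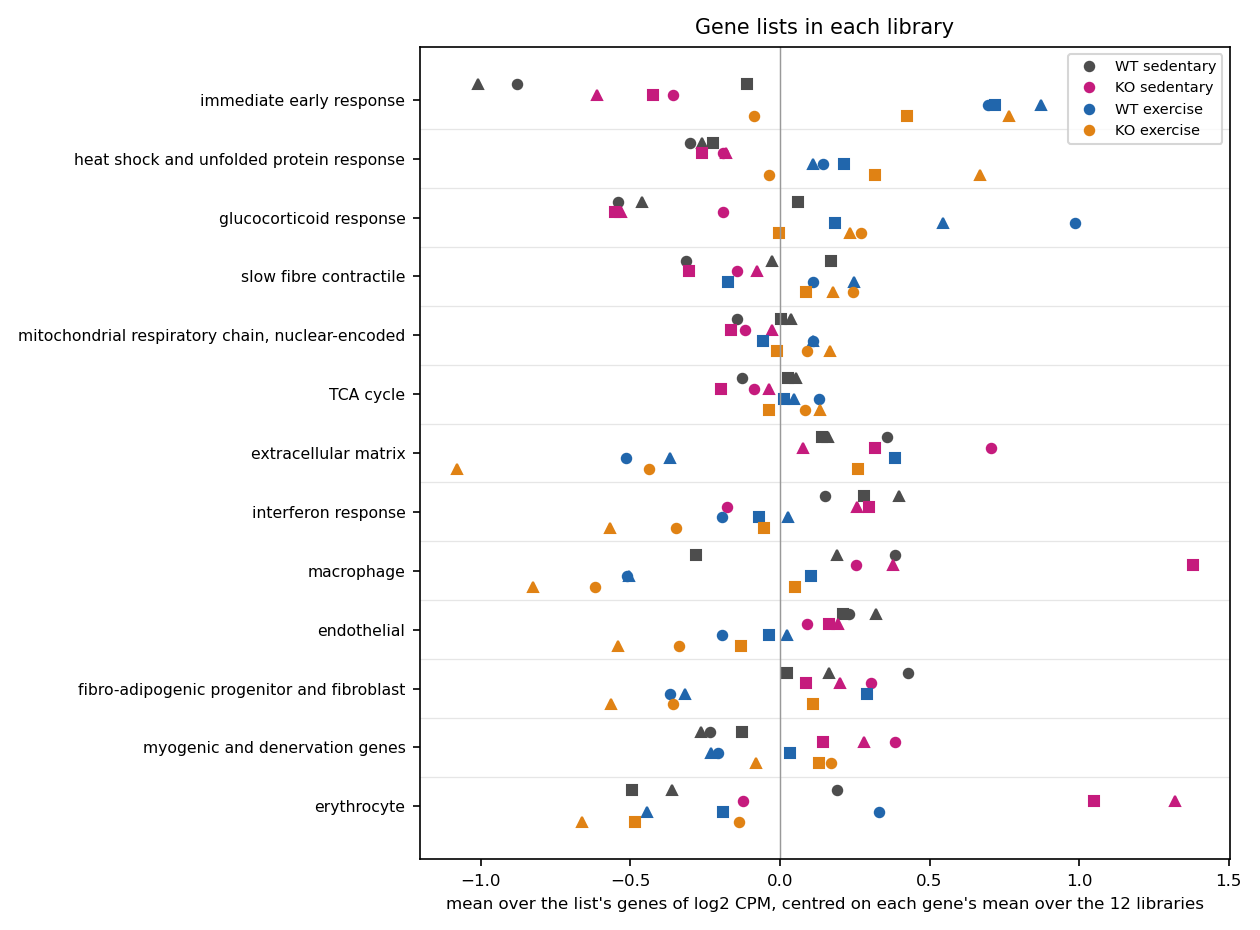
Each row plots, for 1 list, the mean over its genes of log2 CPM centred on each gene's mean over the 12 libraries (x axis), with 1 point per library by group. Immediate early genes differed between exercised and sedentary libraries with a median change of 0.74, and endothelial genes with one of −0.42.

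The interaction of genotype and exercise asks whether the response to exercise differs between KO and WT. By edgeR 0 genes passed, with 430 at an unadjusted p under 0.05 and a smallest adjusted p of 1; DESeq2 called 22, all negative, and limma-voom 0. The genes with the smallest p were Gpx1 (log2 −0.68), which stood at 43.4, 68.4, 51.3 and 50.4 CPM in sedentary WT, sedentary KO, exercised WT and exercised KO muscle, Apbb2, an adaptor that binds the amyloid precursor protein (log2 0.48), Hk3, a hexokinase of leukocytes whose exons overlap Unc5a (log2 −3.38), and Ces1c and Azgp1, both abundant in liver (log2 −11.92 and −10.32). The last 2 follow the libraries rich in Alb, which lie in sedentary KO and exercised WT. For Dnmt3a the difference was 0.37 (SE 0.225) and for Aldh1l1 −0.18 (SE 0.351, both adjusted p = 1). On simulated data without a liver or clock pattern this test recovered 29.2% at 2-fold and 77.3% at 3-fold.

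The KO effects in sedentary and exercised mice, which share no library, were compared across the 13886 genes. Pearson's r was −0.665, Spearman's rho was 0.049, and r was 0.253 without the 3 libraries rich in Alb; genes are not independent replicates. Of 3 genes raised in sedentary and 2 raised in exercised KO muscle, 2 were shared (Ctxn3 and Mttp), where 0.000432 would be expected, and Dnmt3a was the only fall in both. An unadjusted p under 0.05 in both conditions was seen for 128 genes, where 22.7 would be expected, and 58 of them moved the same way. The exercise effects in WT and KO mice had Pearson's r of −0.302, Spearman's rho of 0.507, and r of 0.518 without the libraries rich in Alb. An unadjusted p under 0.05 in both genotypes was seen for 593 genes, where 234 would be expected, and 532 of them moved the same way.

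**Figure D4:**
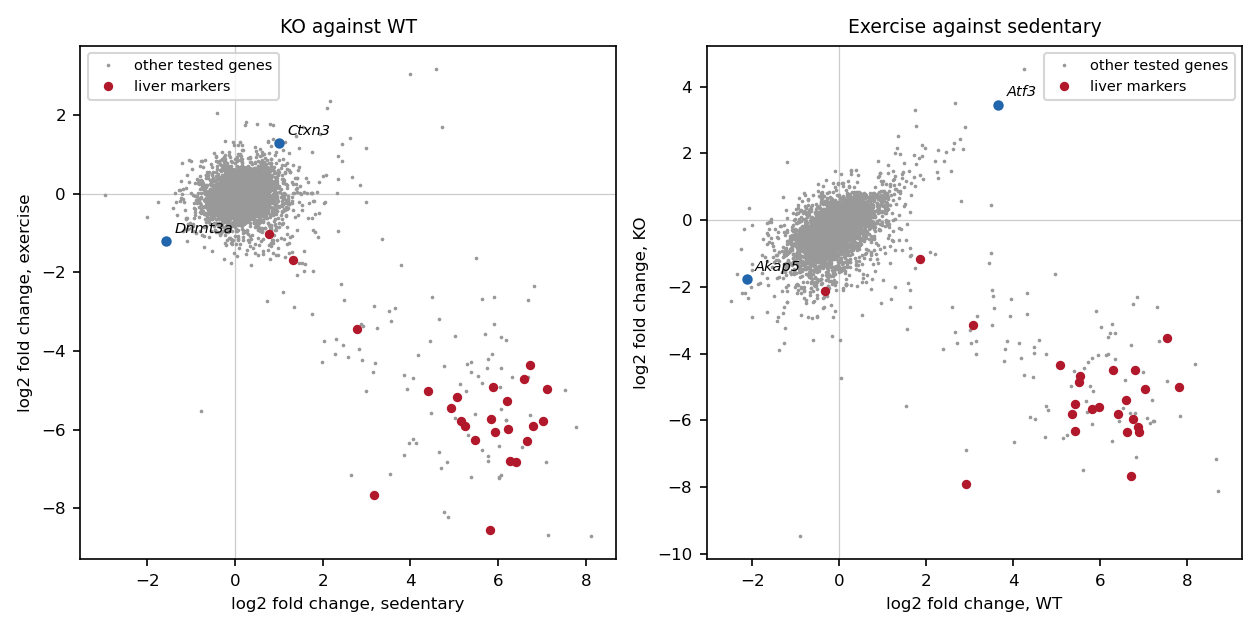
The left panel plots the KO log2 fold change in sedentary (x axis) against exercised mice (y axis), and the right panel the exercise log2 fold change in WT (x axis) against KO mice (y axis), with 1 point per tested gene and liver markers in red. Across genes Pearson's r was −0.665 on the left and −0.302 on the right, and Alb lay at 6.23 and −6.00 on the left and at 6.41 and −5.82 on the right.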

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

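Both tests of the liver pattern, the tests of exercise and of the libraries with 2 animal numbers as causes of the clock pattern, and the fits without the libraries rich in Alb were chosen after the result was seen. The test of time of day and the 3 tests of the endothelial pattern, 2 of them fits with a covariate, were written before.

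For 8 lists the response to exercise differed between KO and WT by camera's test of the interaction with a preset correlation, and for 0 with an estimated correlation (its adjusted p is given as estimated-correlation p). Chance cannot be excluded for that number, since 63 of 100 splits of the libraries gave at least 8 lists, and the highest other gave 17. Erythrocyte genes had a median interaction of −1.40 (camera adjusted p = 7.15e-08, estimated-correlation p = 0.609), with medians of 0.036 for exercise in WT and −1.27 in KO mice. In sedentary KO muscle they stood apart in libraries b and c (1.05 and 1.32 in the mean of centred log2 CPM) and not in a (−0.124). Macrophage genes had −1.0 (camera adjusted p = 0.0017, estimated-correlation p = 0.65), from −0.39 in WT and −1.25 in KO mice. Immediate early genes had −0.518 (camera adjusted p = 0.000459, estimated-correlation p = 0.609), from 1.08 and 0.55. Extracellular matrix genes had −0.335 (camera adjusted p = 0.0279, estimated-correlation p = 0.705), from −0.32 and −0.66. Slow fibre genes had 0.255 (camera adjusted p = 0.00725, estimated-correlation p = 0.705), from 0.15 and 0.34. Respiratory chain genes had 0.11 (camera adjusted p = 8.69e-06, estimated-correlation p = 0.705), from 0.083 and 0.18. Fatty acid genes had 0.108 (camera adjusted p = 0.00469, estimated-correlation p = 0.705), from −0.012 and 0.069. TCA cycle genes had 0.104 (camera adjusted p = 0.0375, estimated-correlation p = 0.705), from 0.056 and 0.16. Over all genes 0 members passed by edgeR, and within the list only the 8 erythrocyte genes did, several of which share reads. With 1 library left out the call was lost for immediate early genes without KO exercise a (median −0.31), macrophage genes without KO exercise c (−0.83, and −0.34 with the call kept without KO sedentary b) and respiratory chain genes without WT exercise b (0.062, with the call kept at 0.069 without KO exercise c and 0.169 without WT sedentary a). It was lost for slow fibre genes without KO sedentary b, WT exercise b or WT sedentary b (0.13 to 0.19), fatty acid genes without KO exercise c, KO sedentary b, WT exercise c or WT sedentary c (0.032 to 0.10), extracellular matrix genes without KO exercise a, KO exercise c, KO sedentary a, WT exercise b, WT sedentary b or WT sedentary c (−0.29 to 0.047), and TCA cycle genes without each of 7 libraries (0.060 to 0.11). With the call kept, the median moved by more than 1.5 times for immediate early genes without KO exercise c (−0.784) or WT sedentary b (−0.839), matrix genes without KO exercise b (−0.734), TCA cycle genes without KO exercise b (0.164) or WT sedentary a (0.174) and fatty acid genes without WT exercise b (0.188). Without the 3 libraries rich in Alb, which leaves 1 exercised WT and 2 sedentary KO libraries, the medians were 0.029 for respiratory chain, 0.045 for fatty acid and 0.16 for slow fibre genes, all without a call, and those of macrophage (0.016), extracellular matrix (0.0775) and TCA cycle genes (−0.014) turned.

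Transcripts of liver stood far above the rest in KO sedentary b, WT exercise b and WT exercise c. A change shared by the mice of a group is argued against by the 18.4-fold difference in the summed CPM of 25 liver markers within exercised WT, and by one of 15.3-fold within sedentary KO. RNA or reads from liver may be the source, since 22 of the 25 markers stood at least 4-fold above the median of the other 9 libraries in all 3 libraries, with Alb at 329, 227 and 178 CPM and a correlation across markers of at least 0.946 between them. In the median of the other 9 libraries 3 of the markers were above 1 CPM. Whether the RNA entered at dissection, in the library or in sequencing stays open, and no biological explanation beyond the group was tested.

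Clock genes differed between libraries of the same group. Dbp stood at 136 to 266 CPM in KO exercise a, WT exercise a, KO sedentary a, WT sedentary b and WT sedentary c and at 18.3 to 25.8 CPM in the others, while Arntl, a clock activator that peaks in antiphase, was lowest in KO exercise a and WT exercise a (12.6 and 7.65 CPM against 31.6 to 76.5). Exercise as the whole cause is argued against by a 14.5-fold range of Dbp among the exercised libraries, and the libraries with 2 animal numbers by an 8.35-fold range among the other 10. Of 12 other clock genes, 12 followed the ratio of Dbp to Arntl with the sign of their limb. Coupled genes do so in any clock shift, so time of day at dissection is not shown. No label gives it, so it stays a hypothesis.

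Endothelial genes were lower in exercised libraries, with 7 of 10 falls within the list and a median of −0.415. With the mean of the fibroblast markers as a covariate 5 falls passed (median −0.329). Fibroblasts alone cannot stand for all non-muscle cells, so a lower share of these stays open. The libraries with 2 animal numbers are argued against by 7 falls without them (median −0.383), and time of day by 9 falls with the ratio of Dbp to Arntl as a covariate (median −0.414). A response of endothelial transcripts to exercise may remain, as a hypothesis found and tested on the same libraries. A lower share of endothelium alone was not tested.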

How the results depend on the processing

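The fits without libraries rich in Alb (over 100 CPM) or with 2 animal numbers, those with a covariate, except the tests of the endothelial pattern, the rank correlations and all fits of the averaged exercise contrast were chosen after seeing the data. No paired analysis was possible because the columns of the count table carry animal numbers that match no replicate number of the labels. Alternatives for values that are not counts did not apply, lists were not run with DESeq2 or glmTreat, correlations have no threshold, and a fit of the compared groups alone equals the full fit where all 4 groups are used. Unless stated, the cause of a change was not tested.

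The fall of Dnmt3a in the averaged genotype contrast was the same in all 26 alternatives (−1.28 to −1.45, highest adjusted p = 0.0022). DESeq2 called 20 genes for KO in sedentary mice, 9 for KO after exercise, 122 for exercise in WT, 359 for exercise in KO, 22 for the interaction, 33 for the averaged genotype contrast and 1012 for the averaged exercise contrast, against 4, 3, 3, 0, 0, 8 and 322 by edgeR. Without the libraries rich in Alb, which leaves 2 sedentary KO libraries and 1 exercised WT library, taken to vary like the other groups, the counts were 2 (KO sedentary), 1 (KO exercise), 11 (exercise in WT), 2 (averaged genotype) and 122 (averaged exercise), and with a liver covariate 2 (KO sedentary) and 1 (KO exercise). Without the libraries of 2 animal numbers they were 0 (exercise in WT), 6 (exercise in KO) and 123 (averaged exercise). A fit of the compared groups alone gave 1 (KO exercise), 6 (exercise in WT) and 7 (exercise in KO). glmTreat, which asks for a larger fold, gave 1 (KO exercise), 0 (exercise in WT), 4 (averaged genotype) and 22 (averaged exercise), and a threshold of 0.1 gave 16 and 955 for the averaged contrasts. Exercise in WT had 0 calls with a clock or a fast fibre covariate, and the averaged exercise contrast 739 with a clock covariate and 496 with library size alone, of which 12.9% were rises against 27.6%.

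Leaving out 1 library gave 1 to 5 genes for KO sedentary (1 without KO sedentary c, and 2 without KO exercise b, KO sedentary b or WT sedentary b), 1 to 4 for KO exercise (1 without KO exercise a or b), 0 to 8 for exercise in WT (8 without WT sedentary b, 6 without KO exercise c, 1 without WT sedentary c, 0 without each of the others), 0 to 4 for exercise in KO (4 without KO exercise a, 2 without KO sedentary a, 1 without WT exercise a, WT sedentary b or WT sedentary c), 0 for the interaction, and 4 to 10 for the averaged genotype contrast (4 without KO exercise a, KO exercise b, KO sedentary b, WT sedentary b or WT sedentary c, 5 without KO sedentary c). For the averaged exercise contrast it gave 45 without WT sedentary c, 66 without KO sedentary b, 84 without KO exercise c or WT exercise c, 94 without WT exercise a, 136 without KO sedentary a, 144 without WT sedentary a, 163 without KO exercise a, 183 without WT sedentary b and 697 without KO exercise b.

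The correlation of the KO effects (−0.665) was −0.272 with no filter, −0.0945 with the compared groups alone, 0.253 without the libraries rich in Alb, −0.227 with a liver covariate and 0.049 by rank, and −0.727 (without KO exercise c) to −0.423 (without KO sedentary b) with 1 library left out. That of the exercise effects (−0.302) was 0.548 with the compared groups alone, 0.518 without the libraries rich in Alb, 0.256 with a liver covariate and 0.507 by rank, and −0.494 to −0.0324 (without KO sedentary b) with 1 library left out.

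Of 2156 values of 82 results for single genes, 1689 were the same, 423 lost and 34 gained a call, and 10 reversed, all without a call. Dnmt3a for exercise in WT was 0.020 without WT sedentary b (from −0.372 without WT exercise c), and for the averaged exercise contrast −0.053 with library size alone (which moves all genes alike, their median from 0.00034 to −0.094), −0.073 without WT exercise c (up to 0.126 without WT sedentary b) and −0.036 without the libraries rich in Alb. Aldh1l1 for exercise in WT was 0.087 without WT exercise c (from −0.377 without WT exercise a), 0.0067 without WT sedentary b, 0.381 without the libraries rich in Alb and 0.177 with a liver covariate; for the interaction it was 0.109 without WT exercise a (from −0.491 without KO exercise a), and for averaged exercise 0.051 without the libraries rich in Alb. Of 2186 values of 89 results for lists, 1945 were the same, 234 lost a call and 7 had camera's direction turned, 6 of them with the median. Extracellular matrix genes for KO exercise had 0.0189 without KO exercise c, 0.116 without WT exercise b (from −0.573 without KO exercise b) and 0.21 without the libraries rich in Alb, where they had 0.0775 for the interaction. TCA cycle genes for the interaction had −0.014 without the libraries rich in Alb and −0.0152 with a liver covariate. Heat shock genes for KO exercise had 0.0349 without KO exercise c (up to 0.189 without KO exercise a), where the median kept its sign. In 8 more values the median alone changed sign. These were extracellular matrix genes for the interaction without WT exercise b (0.047), macrophage genes for the interaction without the libraries rich in Alb (0.016) and with a liver covariate (0.136), and fatty acid genes for exercise in KO without KO sedentary b (−0.019) or the libraries rich in Alb (−0.018). With library size alone they were fatty acid genes for exercise in KO (−0.043), TCA cycle genes for exercise in WT (−0.025) and antioxidant genes for averaged exercise (−0.0034). With 1 library left out and the call kept, 58 medians of lists moved by more than 1.5 times, 20 towards 0 and 38 away. Ctxn3 kept its call in every alternative of the 3 genotype contrasts.

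Depth limits genes with low counts: 13886 of 24539 genes passed the filter.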

Other observations

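The tests of other splits of the libraries were written before their results were seen, except those of list counts outside the averaged contrasts. The averaged exercise contrast and the values of single libraries were chosen after. Several gene lists were not called by camera in either averaged contrast. Fast fibre genes had a median of 0.049 for KO against WT (camera adjusted p = 0.466) and −0.039 for exercise (camera adjusted p = 0.605), and were called without KO sedentary a for genotype (0.13) and without KO sedentary b for exercise (0.14). Without KO sedentary b the genotype median turned to −0.060, and without WT exercise b the exercise median to 0.030. In KO mice alone their change by exercise was called as a fall without KO sedentary a (−0.325) and as a rise without KO sedentary b (0.216). Glycogen and glycolysis genes had 0.068 (camera adjusted p = 0.151) and −0.016 (camera adjusted p = 0.871), with Pgm1, a phosphoglucomutase, down by exercise within the list (log2 −0.44), and a call for genotype without KO exercise b or KO sedentary a (0.11 and 0.13, against 0.0031 without KO sedentary b). Their exercise median ran from −0.067 (without KO sedentary a) to 0.041 (without KO sedentary b). Folate and one-carbon genes had 0.053 (camera adjusted p = 0.0928) and 0.016 (camera adjusted p = 0.427). With 1 library left out they ran from 0.020 (without KO sedentary c or WT sedentary a) to 0.070 (without KO sedentary b) and from 0.0026 (without KO exercise a) to 0.064 (without WT exercise c). Only 4 of 20 germline genes silenced by DNA methylation were expressed enough to be tested, with medians of −0.23 (camera adjusted p = 0.285) and −0.076 (camera adjusted p = 0.785), the latter from −0.157 without KO sedentary b to 0.083 without KO sedentary a. The median of clock genes was −0.045 (camera adjusted p = 0.928) and 0.26 (camera adjusted p = 0.383), with Nfil3 up (log2 2.02) and Bhlhe40 down (log2 −0.38) by exercise within the list. With 1 library left out it ran from −0.44 (without KO exercise a) to 0.14 (without WT exercise a) for KO, and from 0.12 (without KO exercise a) to 0.38 (without KO sedentary a) for exercise. Schwann cell and nerve genes were positive in 10 of 10 for KO (median 0.24, camera adjusted p = 0.192) and negative in 10 of 10 for exercise (median −0.76, camera adjusted p = 0.133). The change by exercise was −0.18 without WT sedentary a and −0.30 without KO sedentary b, and it was called without KO exercise c, KO sedentary a, WT sedentary b or WT sedentary c (−0.99 to −0.91). That for KO was −0.16 without KO sedentary b, and called without WT sedentary a (0.71) or KO sedentary a (0.39). In adipocyte genes the medians were 0.11 (camera adjusted p = 0.331) and −0.87 (camera adjusted p = 0.178). WT sedentary a stood at 1.08 in the mean of centred log2 CPM against −0.40 and −0.76 in its group, and KO exercise c at −1.5 against 0.13 and 0.30. Without WT sedentary a the change by exercise was −0.30, that in WT alone turned from −0.495 to 0.486, and that for KO was called (0.63), as it was without KO exercise c (0.31), but was −0.054 without KO exercise b. The change by exercise was called without WT sedentary c (−1.06).

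The fast fibre gene Myh4 stood at 5500 CPM and Pvalb, a calcium buffer of fast fibres, at 2880 CPM in KO sedentary b, against at most 1740 and 738 CPM elsewhere.

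Other splits of the same libraries were counted for each result. For KO against WT in 3 and 3 libraries the 10 splits are too few for a share under 0.05: in sedentary mice the real split gave 4 genes and the highest other 25, with 2 of 10 splits at least as large, and in exercised mice the real split gave 3 and the highest other 11, again 2 of 10. The same limit holds for exercise in WT (3 genes, highest other 1, 1 of 10 splits) and in KO, where the real split and the highest other gave 0 genes, and for their lists (real and highest other: 9 and 12, 7 and 16, 17 and 12, 20 and 20 in the order above). The split of sedentary mice with 25 genes set KO a with WT b and c, the libraries high in Dbp, against the rest, which points to a structure of the samples that follows the clock. With a covariate for the clock genes 5 genes passed in sedentary mice. For the averaged genotype contrast only 2 of 100 splits, the real one among them, gave at least 8 genes. The other gave 54, so chance is not excluded. It put the 5 libraries high in Dbp and WT exercise b on one side, again a structure of the samples. Chance cannot be excluded for the number of lists in that contrast, where 63 of 100 splits gave at least 8 lists and the highest other gave 17. For the averaged exercise contrast the real split gave 322 genes and the highest other 2, with 1 of 100 splits as large, which argues against chance. Its 20 lists were reached by 3 of 100 splits, with 21 as the highest other. For the interaction the real split gave 0 genes, the minimum, which says nothing about chance. The highest other (81) split each condition into libraries higher and lower in extracellular matrix genes.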
